A study of Mus musculus with 2 samples.

How the data were processed

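Single-cell RNA sequencing was done on CD140a-sorted oligodendrocyte progenitors of tamoxifen-injected mouse pups, with 1 library per genotype (Control and Acly CKO). Per the labels' protocols, droplet libraries were made with the 10x procedure and sequencing aimed at 50000 reads per cell or more. Genotype was taken from the genotype label of each sample. The sample title of the Acly CKO library begins with the word Control as well, and the genotype label was followed. Per the submitters' processing notes, CASAVA 1.8.2 and Cell Ranger 7.1.0 were used with the mm39 build, and per the file headers the matrices were written by Cell Ranger. The deposited values are raw UMI counts per gene and barcode, not normalized and not filtered to cells, for 2554566 barcodes in Control and 2813139 in Acly CKO. Gene symbols and identifiers come from the deposited feature lists, and no coordinates are given because the annotation used here is of another build.

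From these counts, barcodes with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs on mitochondrial genes were kept. Doublets were scored within each library by comparison with simulated doublets (the Scrublet score, own implementation), and a top-scoring share of 0.8% per 1000 cells was removed, which took 762 Control and 914 Acly CKO barcodes. Both libraries were clustered together without integration, on log-transformed counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1. Acly, mitochondrial, Rpl and Rps, haemoglobin, Xist, Tsix and Y-linked genes were left out of clustering. Names starting with Rpl or Rps and a digit counted as ribosomal, Rps27l and the Rps6k kinases included. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.

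Filters, clustering settings, markers, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The scoring that names clusters from the markers was set afterwards. The score of a class in a cluster is the mean, over its detected markers, of the level relative to the highest cluster. OPC-like clusters needed a score of 0.4 and no higher score of an outside class, and those with a cycling score of at least 0.04 were called cycling. Outside classes needed at least 3 detected markers and 2 of them among the top 10 genes by fold, and 2 small clusters stayed unnamed. Low-UMI clusters were OPC-like or cycling OPC-like clusters with a median UMI count under 0.6 of the libraries' median, a boundary also set after clustering, and 0.65 was tried as well.

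UMIs were summed per library and class and expressed as CPM. Sums carry exact Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95%. With 1 library per genotype no test was run and no p-value is given. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs. In OPC-like cells, of genes with at least 30 CPM in a library and at least 50 UMIs, the 12 with the highest and the 12 with the lowest log2 ratio are named, and 5 of each in the cycling class. Mitochondrial, Rpl, Rps, haemoglobin, sex-linked and predicted genes, markers of outside classes and genes at least 5 times higher in an outside class in both libraries were left out. Acly and Acss2 are always named, and of each of 30 gene lists up to 2 members at each end can be. Some genes that these rules take are not reported here. A list's median log2 ratio covers members at 10 CPM or more, its interval comes from 400 Poisson resamples, and its percentile from 10000 random lists of the same size matched on mean expression. The sex-linked list had 4 measured members that went both ways, with a median of 1.67 in OPC-like cells. The calculation was tested on simulated counts of the OPC-like comparison with 200 genes changed among 9691. At true log2 ratios of 1 and 0.5 in either direction, 100% of the changed genes had an interval on the right side of 0, and intervals of unchanged genes covered the truth in 95.3% and those of changed genes in 90% to 100%. The counts were drawn from the Poisson model that the intervals assume, with no variation among cells, animals or libraries. The simulation thus checks the arithmetic and not whether differences between unreplicated libraries are recovered.

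Alternatives were other UMI and gene minimums, mitochondrial limits of 5% and 20%, no doublet removal, resolutions 0.5 and 2, TMM scaling, totals without mitochondrial and ribosomal genes, means over cells, subtraction of free RNA at 5%, thinning, CPM floors of 3 and 30 for list members, a class from the highest marker score, and thinning before clustering. Added after seeing the data were leaving out low-UMI clusters, a cycling boundary of 0.1, leaving out the cluster with the highest p53 target level, and the same weight in both libraries for clusters with at least 50 cells in each, which leaves out the cluster with the highest p53 target level. A value under an alternative counted as moved when it left the 95% counting interval of the value reported, which for means over cells and weighted clusters came from the sums. A band of 5% was used for median UMIs.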

Results

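Oligodendrocyte progenitor cells (OPCs), the dividing cells that give rise to myelinating oligodendrocytes, were sorted from mouse pup forebrain by surface CD140a, the product of Pdgfra. They were profiled by droplet single-cell RNA sequencing. The design compared pups with loxP-flanked Acly alleles and no Cre (Control) with pups that also carried a tamoxifen-inducible Cre driven by Pdgfra (Acly CKO). Acly encodes ATP citrate lyase, which makes cytosolic acetyl-CoA from citrate. Each genotype was represented by 1 library, so no difference below has a replicate check and no test was made. Intervals are 95% intervals and cover counting error only. The labels give the age both as postnatal day 5 and as postnatal days 6 to 8. Control lacked Cre, so Cre activity and loss of Acly cannot be separated by this design.

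The Control matrix held 190058273 UMIs (unique molecular identifiers, 1 per captured transcript) and the Acly CKO matrix 207557744, over 32285 genes. Barcodes with at least 1000 UMIs numbered 10077 and 11213 and held 90.5% and 85.6% of the UMIs. After filters and doublet removal 9000 Control and 9772 Acly CKO barcodes remained. Their median depth was 15665 UMIs and 5139 genes in Control and 14634 UMIs and 4828 genes in Acly CKO. The libraries differed in sex-linked transcripts. In OPC-like cells the Y-linked genes Eif2s3y and Kdm5d had 0 UMIs in Control, and 2114 and 834 UMIs in Acly CKO, which is 31.9 and 12.6 CPM (UMIs per 1000000). Uty had 6 and 2015 UMIs. Ddx3y, also Y-linked, stood at 1.49954 CPM in Control and 19.9 CPM in Acly CKO, and Xist, transcribed from the inactive X, at 1153 and 882 CPM. By Eif2s3y and Kdm5d, male cells were present in Acly CKO and not detected in Control. Sex makeup thus differed along with genotype, which limits each comparison of the libraries below, and it was examined for Esr1 alone.

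The first question was which cells the sort held. OPC-like and cycling OPC-like cells made up 95.8% (95.4 to 96.2) of Control barcodes and 86.3% (85.6 to 87.0) of Acly CKO barcodes, with exact binomial intervals. Fibroblast-like cells, which also expressed Pdgfra, made up 3.10% (2.75 to 3.48) and 4.91% (4.49 to 5.36). A cluster led by haemoglobin genes, with a median of 1136 UMIs, held 0.144% of Control and 7.35% of Acly CKO barcodes. Its barcodes also carried OPC transcripts, with an OPC score of 0.363, below the cut of 0.4, Pdgfra at 804 and 423 CPM and Fabp7 at 7419 and 10935 CPM. The 13 Control barcodes held no UMI of the haemoglobin gene Hbb-bs, which stood at 6292 CPM in Acly CKO. Free RNA, read from barcodes with 1 to 50 UMIs, held Pdgfra at 897 CPM in Control and 816 CPM in Acly CKO, above the cluster in both. The Pdgfra counts thus do not show that these barcodes were OPC-like cells. The lower share of OPC-like and cycling OPC-like cells in Acly CKO depends in part on whether these barcodes are counted. Outside this cluster, OPC-like and cycling OPC-like cells made up 95.9% and 93.2%. The naming rule had no class for committed OPCs or oligodendrocytes, so whether such cells were present was not examined by it. Gpr17 and Bcas1, markers of committed OPCs, were among the leading genes of some OPC-like clusters. Microglia-, ependymal- and neuroblast-like clusters held at most 27 cells each in either library. The CD140a gate and the UMI minimum set these shares in part, and with a minimum of 500 UMIs the share of OPC-like and cycling OPC-like cells was 94.5% in Control and 48.0% in Acly CKO. The direction depended on the naming of classes. The shares were 66.1% and 76.2% at a mitochondrial limit of 5%, where 29.7% and 8.66% of barcodes lay in unnamed clusters with OPC scores. With each barcode given the class of its highest marker score they were 34.9% and 39.7%. That rule had committed OPC, oligodendrocyte and neural progenitor classes, which counted as outside, and took any barcode led by cycling markers as cycling OPC-like. Its shares are thus not of the same measure.

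Among OPC-like and cycling OPC-like barcodes, the cycling class, which carried transcripts of cell division such as Top2a and Mki67, made up 31.9% (30.9 to 32.9) in Control and 40.1% (39.0 to 41.1) in Acly CKO. These were 2752 of 8623 and 3380 of 8437 barcodes. The class boundary was set after cluster scores were seen, and clusters just above it held 14.3% of these barcodes in Control and 13.9% in Acly CKO. With a higher boundary that leaves those clusters out, the cycling shares were 17.6% and 26.2%. The gap between the libraries was smaller at a mitochondrial limit of 5%, with 38.3% and 41.5%, and almost gone without doublet removal, with 44.1% and 45.1%. In both settings unnamed clusters with OPC scores were left out of these shares, and unevenly. They held 29.7% of Control and 8.66% of Acly CKO barcodes at the 5% limit, and 28.5% and 8.17% without doublet removal. The smaller gaps thus do not compare like with like.

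Clusters with low UMI counts took a larger share in Acly CKO. OPC-like clusters under 0.6 of the median depth held 712 Control and 1780 Acly CKO barcodes, which is 8.26% (7.68 to 8.86) and 21.1% (20.2 to 22.0) of the OPC-like and cycling OPC-like barcodes. With a boundary of 0.65, which takes in 1 cycling cluster, the shares were 9.61% and 25.9%. In Control, ribosomal protein transcripts took 1.87% of UMIs in the low-UMI clusters and 8.75% in the others, and mitochondrial transcripts 5.01% and 2.62%. In Acly CKO the ribosomal shares were 2.38% and 9.74%, and the mitochondrial shares 4.80% and 2.62%.

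Acly (ENSMUSG00000020917) was lower in Acly CKO in the classes that express Pdgfra. In OPC-like cells it stood at 71.9 CPM (70.1 to 73.7) in Control, from 6230 UMIs, and 28.3 CPM (27.1 to 29.6) in Acly CKO, from 1876 UMIs, with exact Poisson intervals. That is 39.4% of Control (37.4 to 41.5). In cycling OPC-like cells it was 61.0 and 20.7 CPM, 34.0% of Control (31.9 to 36.2). In fibroblast-like cells it was 47.3 and 7.37 CPM, 15.6% of Control (11.6 to 20.7). Microglia-, neuroblast- and ependymal-like cells, each too few by the 50-cell minimum, were pooled after their numbers were seen, and Acly there was 58.8 CPM (42.9 to 78.7) and 51.2 CPM (37.2 to 68.7). The pool differed in makeup, with 20 Control and 14 Acly CKO microglia-, 7 and 25 neuroblast- and 17 and 27 ependymal-like cells, so its values do not compare like with like. By class Acly stood at 67.4% of Control (22.8 to 167), 361% of Control (52.4 to 15526) and 109.6% of Control (57.6 to 214). A difference was not detectable in any of them at this depth. Free RNA, read from barcodes with 1 to 50 UMIs, held Acly at 50.2 CPM (43.5 to 57.5) in Control and 11.8 CPM (9.07 to 15.04) in Acly CKO. The labels do not say which exons were flanked, so a 3′ tag may lie outside the deleted part.

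**Figure D1:**
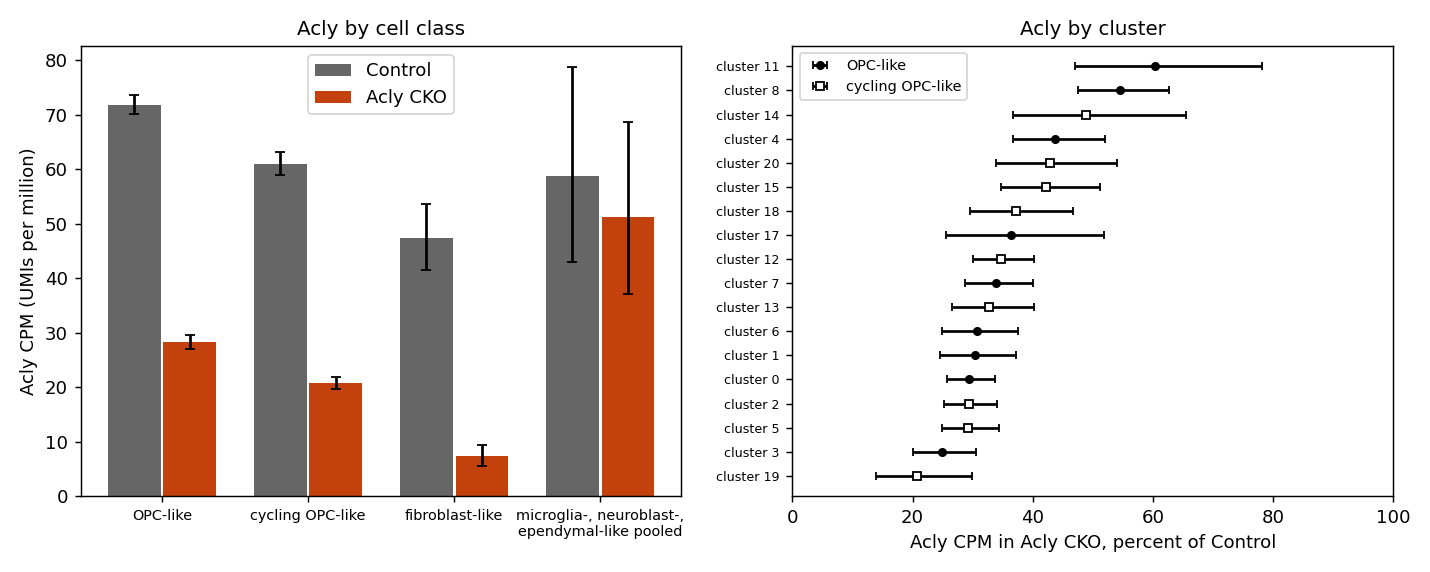
Left, Acly CPM (UMIs per 1000000, y axis) per cell class in 1 Control and 1 Acly CKO library, with exact 95% Poisson intervals. Right, Acly CPM in Acly CKO as percent of Control (x axis) for each OPC-like or cycling OPC-like cluster with at least 50 cells in both libraries, with 95% counting intervals. Acly stands at 71.9 CPM in Control and 28.3 CPM in Acly CKO in OPC-like cells, and cluster values run from 20.7% to 60.4%.

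After each cell was thinned to 2000 UMIs, an Acly UMI was found in 12.6% (11.8 to 13.5) of Control and 5.80% (5.17 to 6.48) of Acly CKO OPC-like cells. Shallower cells left out numbered 18 and 19. Unthinned, the shares were 60.6% and 27.8%, at median depths of 14614 and 13150 UMIs. No class that lacks Acly by nature was present to give a background share, and the lowest thinned share, in fibroblast-like cells of Acly CKO, was 1.46% (0.588 to 2.98) at a median depth of 16649 UMIs. The Acly level was uneven across OPC-like clusters. In cluster 8, whose leading genes included Dll3 and Dll1, Acly stood at 77.9 CPM in Control and 42.5 CPM in Acly CKO, 54.6% of Control. In cluster 11, a low-UMI cluster, it stood at 60.4% of Control, and in clusters 0, 1 and 3 at 29.4%, 30.4% and 24.95%. Acss2, which makes acetyl-CoA from acetate, stood at 20.6 CPM in Control and 20.5 CPM in Acly CKO in OPC-like cells, a log2 ratio of -0.0072 (-0.11 to 0.10). In cycling OPC-like cells its log2 ratio was -0.20 (-0.34 to -0.061).

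Gene levels were then compared in OPC-like cells outside the cycling class, with 5871 Control and 5057 Acly CKO cells. Genes were ranked after leaving out, among others, sex-linked genes and genes at least 5 times higher in an outside class in both libraries. The highest ratio in this ranking belonged to Cdkn1a (ENSMUSG00000023067), which encodes the cell cycle inhibitor p21. It stood at 2.43 CPM in Control and 44.3 CPM in Acly CKO, a log2 ratio of CPM (Acly CKO over Control) of 4.19 (3.98 to 4.395). Esr1 (ENSMUSG00000019768), the oestrogen receptor gene, stood at 2.62 and 31.9 CPM, a log2 ratio of 3.61 (3.41 to 3.81). The ligand-binding part of an oestrogen receptor is also part of tamoxifen-inducible Cre proteins, and reads of the transgene were not told apart from Esr1. Of 9678 genes at 10 CPM or more, the central 95% of log2 ratios ran from -0.44 to 0.38, with a median of -0.042. The largest clusters of the class differed in part between the libraries. In Control they were clusters 1, 0 and 3, with 1349, 1243 and 1054 cells, and in Acly CKO clusters 4, 0 and 8, with 920, 835 and 626 cells.

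Genes among the 12 highest also included Egfr, the epidermal growth factor receptor gene (log2 ratio 1.36), Pvt1 (1.26), Cdon (1.15), Map3k20 (1.13), Draxin (1.04), Ano3 (1.01), Nkain2 (0.996), Aen (0.94) and Pola1, a DNA polymerase subunit gene (0.82). Ano3 was also among the leading genes of an OPC-like cluster. In this ranking Acly had the lowest ratio, -1.34 (-1.42 to -1.27). Others among the 12 lowest were Pcp4 (-1.15), Nfatc2 (-1.09), the homeobox gene Irx1 (-1.04), S100b (-0.99), the connexin gene Gjc3 (-0.85), Ajap1 (-0.82), Fxyd7 (-0.80), Tmem100 (-0.78), Arl4a (-0.76), Rasgrf1 (-0.73) and the Notch target Hes5 (-0.71). Socs3 (-2.03) and Fosb (-1.26) were lower than genes in this list but stood outside the ranking, since both were at least 5 times higher in fibroblast-like cells. A comparison added after seeing the data gave OPC-like clusters the same weight in both libraries. There Nkain2 changed sign (-0.13), Egfr stood at 0.16, Draxin at 0.057, Irx1 at -0.22, Fxyd7 at -0.12, Hes5 at -0.21 and Cdkn1a at 2.18. In the same comparison Acly stood at -1.45, Esr1 at 3.68 and Nfatc2 at -1.02. At a mitochondrial limit of 5%, Irx1 stood at -0.14, Fxyd7 at -0.20 and Gjc3 at -0.31, and without the low-UMI clusters Pola1 stood at 0.26. At the 5% limit, and without doublet removal, unnamed clusters with OPC scores were missing from the OPC-like and cycling OPC-like classes. Values under these settings, here and below, thus come from another set of cells.

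**Figure D2:**
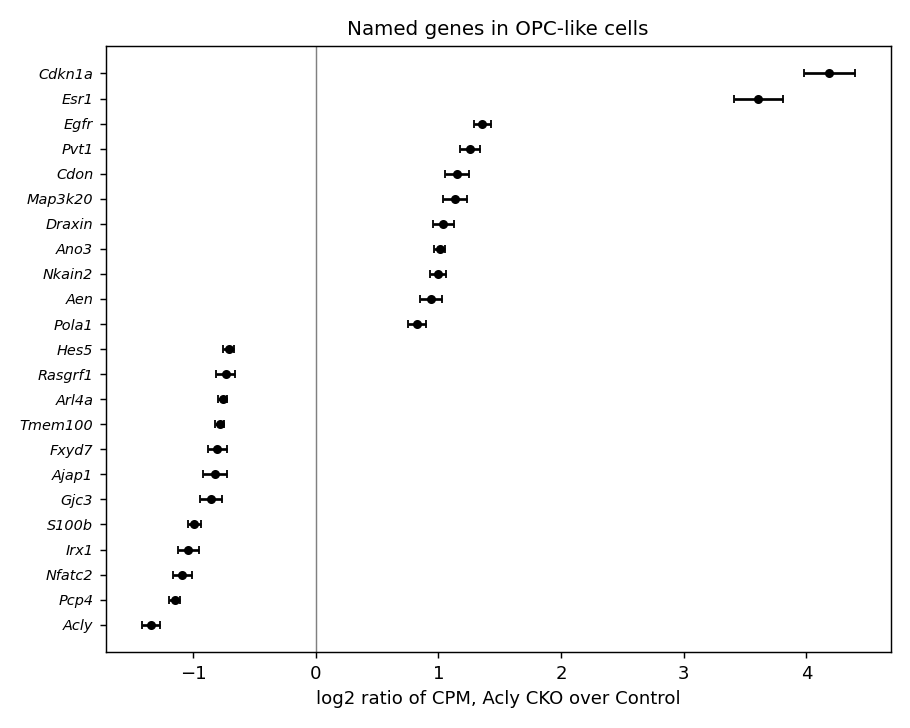
Log2 ratio of CPM, Acly CKO over Control (x axis), of genes named among the 12 with the highest and the 12 with the lowest ratio in OPC-like cells (y axis), 1 library per genotype. Points are ratios and bars 95% counting intervals. Cdkn1a (4.19) and Esr1 (3.61) lie apart from the other genes, and Acly (-1.34) is lowest of the genes drawn.

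Targets of the transcription factor p53 were higher in OPC-like cells of Acly CKO. Of the measured members, 14 of 16 had a higher level, and the median log2 ratio was 0.44 (0.42 to 0.46), above all 10000 random lists of the same size matched on expression. This rank, like the others below, describes these libraries only. Besides Cdkn1a, Polk had a log2 ratio of 1.03, Ptp4a3 of -0.13 and Plk2 of -0.22. Much of this median came with 1 cluster of 12 Control and 392 Acly CKO cells, the one with the highest level of these targets. Without it the median was 0.12 and the ratio of Cdkn1a 2.33, and with the clusters given the same weight, which leaves this cluster out as well, the median was 0.18. It was 0.60 without the low-UMI clusters, and with members at 30 CPM or more 0.23. By cluster the median was 0.21 (0.15 to 0.29) in cluster 0, 0.21 (0.078 to 0.29) in cluster 1 and 0.18 (0.057 to 0.23) in cluster 3, but 0.011 (-0.044 to 0.080) in cluster 8. After thinning to 2000 UMIs, a Cdkn1a UMI was found in 0.325% (0.196 to 0.506) of Control and 5.16% (4.57 to 5.81) of Acly CKO OPC-like cells, against 1.60% and 11.6% unthinned. In fibroblast-like cells the thinned shares were 5.73% (3.31 to 9.15) and 3.75% (2.24 to 5.86), at median depths of 17772 and 16649 UMIs.

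Genes of cholesterol synthesis were slightly lower in OPC-like cells of Acly CKO as a class, but not in each cluster. Of the measured members 20 of 21 had a lower level, with a median log2 ratio of -0.14 (-0.17 to -0.11), at percentile 0.91 of the random lists, and of -0.080 with the clusters given the same weight. With cells thinned to 2000 UMIs the median was -0.10, at percentile 20.19, and without doublet removal -0.073. By cluster it was 0.016 (-0.015 to 0.087) in cluster 0 and 0.0053 (-0.067 to 0.077) in cluster 1, -0.16 in cluster 3, -0.29 in cluster 6, -0.33 in cluster 17 and -0.54 in cluster 11. Hsd17b7 had a log2 ratio of -0.45, Fdps of -0.0067 and Ebp of 0.078. The fatty acid synthesis list had a median of -0.084 (-0.11 to -0.049), at percentile 14.97, with 16 of 20 members lower. Mid1ip1 stood at -0.36 and Acaca, acetyl-CoA carboxylase, at 0.16. Without the low-UMI clusters the median was -0.17, at percentile 0.07, Acaca stood at -0.015 and Mid1ip1 at -0.20, and with cells thinned to 2000 UMIs the median was -0.033. The acetyl-CoA supply list had a median of -0.084, at percentile 15.62, with 19 of 23 members lower, Acly among them, Me1 at -0.24, Dlat at 0.056 and Acss1 at 0.11. The list for SREBP regulation and sterol uptake stood at -0.046 (percentile 47.65), with Stard4 at -0.45 and Lpin1 at 0.29. Sterol efflux genes stood at -0.10 (percentile 20.32) and sphingolipid and galactolipid synthesis genes at -0.015 (percentile 71.99). The last of these kept its sign in 13 of the 19 alternatives run for it and reached 0.084 (percentile 99.93) with the clusters given the same weight, where the acetyl-CoA supply list stood at -0.012. The SREBP list changed sign to 0.0057 with cells thinned to 2000 UMIs, and sterol efflux genes to 0.0022 without doublet removal. Without the low-UMI clusters sterol efflux genes stood at -0.19 (percentile 1.30), the SREBP list at -0.090 and sphingolipid and galactolipid synthesis genes at -0.063.

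Genes of the early steps of differentiation were lower. The list of committed OPC and early oligodendrocyte genes had a median of -0.26 (-0.28 to -0.21), below all 10000 random lists, with 13 of 19 members lower. Neu4 stood at 24.1 CPM in Control and 11.47 CPM in Acly CKO (-1.07), and Gpr17, a receptor gene of committed precursors, at 256 and 171 CPM (-0.58). Dll3 (0.41) and Epb41l2 (0.30) were the highest members. With the clusters given the same weight the list median was -0.16 and Dll3 stood at -0.022. At a mitochondrial limit of 5%, where some clusters with OPC scores stayed unnamed and outside the class, the list median was -0.12. Dll3 and Gpr17 were also among the leading genes of OPC-like clusters. Those with Gpr17, clusters 1, 3 and 6, held 1349, 1054 and 666 Control cells and 292, 364 and 318 Acly CKO cells. Those with Dll3, clusters 7 and 8, held 507 and 328 Control cells and 450 and 626 Acly CKO cells. Values over the whole class thus mix its makeup with levels within clusters. Of the measured myelin genes 8 of 9 were lower, with a median of -0.28 (percentile 0.02), among them Gjc3 (-0.85) and Gsn (-0.45). The myelin median was -0.11 (percentile 2.44) with the clusters given the same weight. Positive regulators of differentiation stood at -0.14 (percentile 1.21), with the lineage factor gene Sox10 at 414 and 265 CPM (-0.65) and Nkx2-2 at -0.54. Inhibitors of differentiation stood at -0.22 (percentile 0.04), with the Notch targets Hes1 (-0.70) and Hes5 (-0.71) lowest and Id4 (0.51) highest. This list was lower in fibroblast-like cells as well (-0.27). Without the low-UMI clusters the medians were -0.060 for the positive regulators and -0.11 for the inhibitors. The OPC identity list stood at -0.062 (percentile 10.74), at -0.10 (percentile 0.20) without the low-UMI clusters and at 0.021 without doublet removal, and the gate gene Pdgfra at 1499 and 1624 CPM.

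Cell cycle lists were higher in the OPC-like class although cycling clusters had been set aside. The S phase list had a median of 0.40 (20 of 22 members higher), with Mcm3 at 1.03 and Atad2 at 0.97. It stood at 0.13 without the low-UMI clusters, where Mcm3 had a ratio of 0.34 and Atad2 of 0.047. The G2 and M phase list had a median of 0.20 (17 of 20 higher), with Ube2c at 1.39 and Birc5 at 1.38. Both lay above all 10000 random lists. Their medians moved with the members taken, to 0.13 and 0.063 at 30 CPM or more and to 0.61 and 0.70 at 3 CPM or more. With minimums of 500 UMIs and 250 genes the G2 and M phase median was 0.025, at percentile 89.61. Members of these lists also help to set the boundary between the classes. Histone acetyltransferase genes, whose products use acetyl-CoA, stood at 0.059 (percentile 97.47), with Hat1 at 0.41 and Kat2a at -0.20, and at 0.025 with the clusters given the same weight. Histone deacetylase genes stood at -0.15 (percentile 2.43), with Hdac11 at -0.43 and Hdac9 at 0.40, and at -0.077 without the low-UMI clusters, where Hat1 stood at 0.034 and Hdac9 at 0.13.

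Lists of energy metabolism stood slightly below 0, at -0.094 for fatty acid oxidation (percentile 14.72), -0.11 for glycolysis (4.2), -0.080 for the TCA cycle (17.04) and -0.11 for nuclear genes of oxidative phosphorylation (0.09). The last of these changed sign to 0.046 without the low-UMI clusters, and with the clusters given the same weight the others stood at -0.027, -0.012 and -0.0092. Immediate early and dissociation response genes were lower in Acly CKO, with a median of -0.28 (17 of 21 members lower, below all 10000 random lists), Socs3 at -2.03 and Fosb at -1.26. The median was -0.13 without the low-UMI clusters and -0.40 with the clusters given the same weight. By cluster it ran from -0.59 in cluster 4, a low-UMI cluster, to -0.067 in cluster 8, with -0.48 in cluster 0 and -0.40 in cluster 1, which are not low-UMI clusters. The ATF4 list stood at -0.17 (percentile 0.28), with Atf4 itself at -0.59, and at -0.076 without the low-UMI clusters. The unfolded protein response stood at -0.090 (percentile 11.63), hypoxia response at -0.14 (4.23) and the NRF2 list at -0.090 (10.72). Without the low-UMI clusters these were -0.16, -0.022 and 0.011. With means over cells glycolysis stood at -0.20, oxidative phosphorylation at -0.20, the NRF2 list at -0.20 and positive regulators of differentiation at -0.21. The unfolded protein response changed sign to 0.028 (percentile 81.59) with cells thinned to 2000 UMIs. Interferon genes had 4 measured members and a median of -0.0019, which moved to 0.056 with members at 3 CPM or more and to -0.16 without the cluster richest in p53 targets. Glutamate receptors and channels stood at 0.064 (97.74), at -0.089 without the low-UMI clusters and at 0.17 without doublet removal, and of matrix and adhesion genes 11 of 18 were lower, with a median of -0.040 at percentile 30. Of the same genes 17 of 18 were lower without the low-UMI clusters, with a median of -0.17 at percentile 0.02, and with cells thinned to 2000 UMIs the median was 0.038. The list of free RNA and quality genes stood at -0.019 (percentile 37.29), and with cells thinned to 2000 UMIs at 0.085. Mitochondrial transcripts took 2.82% of the UMIs of the class in Control and 3.13% in Acly CKO, and ribosomal protein transcripts 8.53% and 8.83%.

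**Figure D3:**
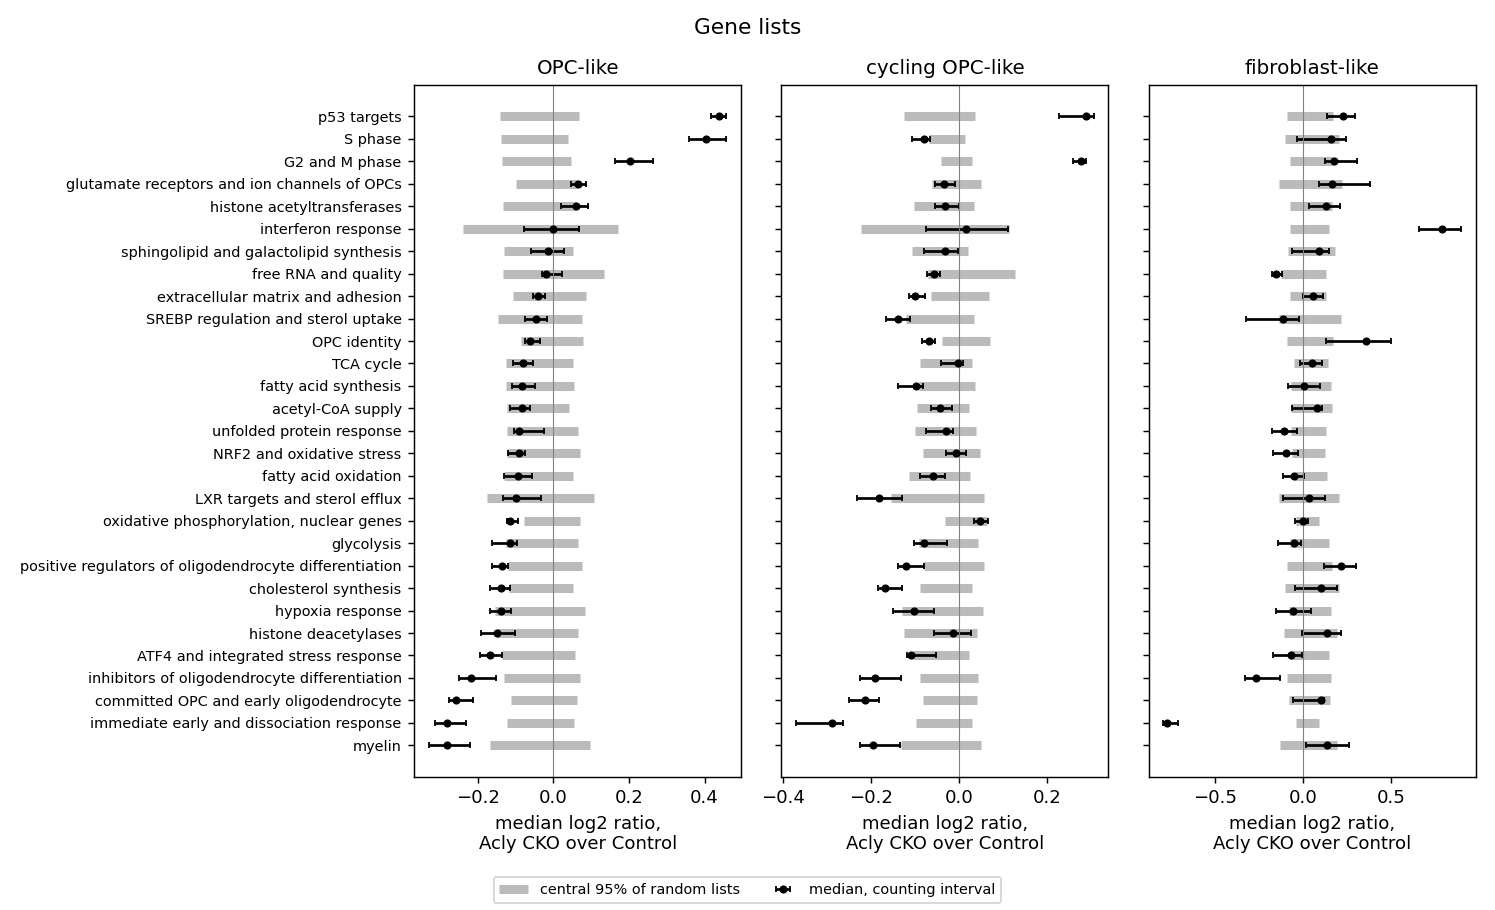
Median log2 ratio of CPM, Acly CKO over Control (x axes), of gene lists (y axis) in OPC-like, cycling OPC-like and fibroblast-like cells of 1 library per genotype. Points with bars are medians with 95% counting intervals, and grey bars are the central 95% of 10000 random lists matched on expression. Of the lists drawn, p53 targets have the highest median in OPC-like cells (0.44), and interferon response genes in fibroblast-like cells (0.79).

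In cycling OPC-like cells several lists went the same way. p53 targets had a median of 0.29 (0.23 to 0.31), with 11 of 15 members higher, Cdkn1a at a log2 ratio of 1.93 and Aen at 0.54. Cholesterol synthesis stood at -0.17 (-0.18 to -0.13) with 16 of 20 members lower, although at 0.019 in cluster 2, fatty acid synthesis at -0.10 (percentile 1.6) and the committed OPC list at -0.21 with 16 of 19 members lower. The G2 and M phase list stood at 0.28 with 49 of 51 members higher, and the S phase list at -0.078 with 30 of 40 lower. With the clusters given the same weight the G2 and M phase median was 0.031 and that of p53 targets 0.32. With members at 30 CPM or more the median of p53 targets was 0.085 (percentile 99.18). TMM scaling, which moved all ratios of this class alike, gave -0.10 for cholesterol synthesis, -0.033 for fatty acid synthesis and -0.014 for the S phase list, which stood at -0.14 at a mitochondrial limit of 5%. The 5 highest genes of the ranking were Esr1 (4.01) and the histone genes Hist1h1d (0.70), Hist1h3e (0.69), Hist1h1b (0.65) and Hist1h2ae (0.64), of which Hist1h1b and Hist1h2ae also led 1 cycling cluster. The 5 lowest were, in the same ranking, Acly (-1.56), Nfatc2 (-1.24), Pcp4 (-0.87), the signalling factor gene Stat3 (-0.79) and Bcl6 (-0.72). Outside it, Socs3 stood at -1.96, Fosb at -1.72, Fos at -1.36 and Junb at -1.30.

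Fibroblast-like cells, 279 in Control and 480 in Acly CKO, gave the comparison within the same libraries. As Acly was lower there too, they are not an untargeted class. Interferon response genes were higher in Acly CKO, with a median of 0.79 (0.66 to 0.89), 18 of 19 members higher, Bst2 at 1.72 and Xaf1 at 1.62. Immediate early and dissociation response genes were lower, with 28 of 28 measured members below Control and a median of -0.77 (-0.79 to -0.71). p53 targets had a median of 0.23 (0.14 to 0.30), with 11 of 15 higher, Aen at 0.99 and Plk2 at -1.40. Cdkn1a stood at 25.6 and 26.6 CPM there, a log2 ratio of 0.054 (-0.26 to 0.38). Cholesterol synthesis stood at 0.10 (-0.044 to 0.20) and the committed OPC list at 0.11 (-0.053 to 0.12). Inhibitors of differentiation stood at -0.27 (-0.33 to -0.13), at percentile 0.01, with 7 of 12 members lower. In the alternatives their median ran from -0.41 to -0.0097. Genes of OPC identity had a median of 0.36 (0.13 to 0.50) in the fibroblast-like cells, with Lhfpl3 at 1.26. This did not hold with minimums of 2000 UMIs and 1000 genes, where the median was 0.017 (percentile 34.35). Olig1, a member of the list of positive regulators of differentiation, stood at 1.30. With cells thinned to 2000 UMIs the committed OPC list changed sign to -0.067 and p53 targets stood at 0.14 (percentile 82.16). Without doublet removal cholesterol synthesis stood at 0.0094.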

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

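The tests on Esr1 in this part were set before their results were seen, and the other tests after. The median log2 ratio (Acly CKO over Control) of positive regulators of oligodendrocyte differentiation was -0.14 in OPC-like cells and 0.22 in fibroblast-like cells, opposite directions whose difference was not tested. With cells thinned to 2000 UMIs the median in fibroblast-like cells was 0.0035 (percentile 40.8). A cluster led by haemoglobin genes, which enters no comparison of gene levels, held 0.144% of kept barcodes in Control and 7.35% in Acly CKO.

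The higher level of p53 targets in OPC-like cells (median 0.44) was weighed against 4 explanations. Without the low-UMI clusters the median was 0.60, which argues against low-UMI barcodes as the source. Without the cluster held almost wholly by Acly CKO it was 0.12 (0.095 to 0.16), and with the remaining clusters given the same weight 0.18 (0.15 to 0.22). Both lay above the central 95% of the random lists of the same comparison (upper bounds 0.076 and 0.056). That cluster was picked for the highest level of these same targets, so a fall without it was set in advance. Cdkn1a stood at 342 CPM in its 12 Control cells and 357 CPM in its 392 Acly CKO cells. The values that remain show that this cluster may account for much of the difference but not the whole. The mix of the remaining clusters is argued against as the source of the rest. In fibroblast-like cells, whose Acly was lower as well, the median was 0.23 (0.14 to 0.30), which leaves open a difference that all cells of a library share, although Cdkn1a stood at 0.054 (-0.26 to 0.38) there. Loss of Acly and Cre activity, which the design does not separate, stay open too, as does the sex makeup of the libraries, which was not tested for these genes.

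The Esr1 counts in Acly CKO may come from the CreER transgene, whose receptor part resembles Esr1. This predicted a lower level in cells that express little Pdgfra, and Esr1 stood at 5.82 CPM (1.89 to 13.6) in pooled microglia-, neuroblast- and ependymal-like cells of Acly CKO, from 5 UMIs, against 31.9 CPM (30.5 to 33.3) in OPC-like cells. In Control the pooled cells stood at 10.5 CPM (4.51 to 20.6). In fibroblast-like cells, with Pdgfra at 504 CPM in Acly CKO, Esr1 stood at 0.196 CPM in Control, from 1 UMI. In Acly CKO it stood at 22.1 CPM there (19.0 to 25.6), from 183 UMIs. As Acly was lower in these cells too, this does not separate transgene reads from a response of the gene. The sex makeup is argued against, since Esr1 CPM in OPC-like cells of Acly CKO with a Y-linked UMI was 0.974 times that in cells with none (0.887 to 1.07). Which receptor sequence the transgene holds is not given in the sources used here, and a response of the Esr1 gene itself stays open.

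Low-UMI clusters held 8.26% of OPC-like and cycling OPC-like barcodes in Control and 21.1% in Acly CKO. Ordinary cells captured with fewer UMIs are argued against, because the ribosomal protein share in the other clusters was at least 4.10 times that in the low-UMI clusters in both libraries. Nuclei free of cytoplasm are argued against as well, because the mitochondrial share in the low-UMI clusters was at least 1.83 times that in the others. Malat1, a nuclear RNA, stood at 34758 CPM in these clusters and 16713 CPM in the others in Control. Damaged cells that lost cytoplasm, which these shares leave possible, and a difference between the genotypes stay open.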

How the results depend on the processing

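The alternatives that leave out low-UMI clusters or the cluster rich in p53 targets, raise the cycling boundary or give clusters the same weight were chosen after seeing the data. Acly in OPC-like cells stayed between -1.50 and -1.17 (log2 ratio) in the 17 alternatives run for it. The medians of p53 targets (0.12 to 0.60), fatty acid synthesis (-0.17 to -0.033), cholesterol synthesis (-0.17 to -0.073) and committed OPC genes (-0.26 to -0.10) in OPC-like cells kept their sign in the 19 run for each. The median of all genes at 10 CPM or more was itself -0.042 there, so a kept negative sign alone does not set a list apart. Percentiles reached 55.46 for fatty acid synthesis, 20.19 for cholesterol synthesis and 3.23 for committed OPC genes, and were at least 99.74 for p53 targets. The cycling share was higher in Acly CKO than in Control in each alternative run for it. The share of OPC-like and cycling OPC-like barcodes, called the lineage share, was lower in Control than in Acly CKO in 4 alternatives, against the direction reported. In 3 of them, with at most 5% mitochondrial UMIs, without doublet removal and with thinning before clustering, clusters with OPC scores stayed unnamed, with 29.7%, 28.5% and 29.3% of Control and 8.66%, 8.17% and 12.7% of Acly CKO barcodes. Gene and list values at the 5% limit and without doublet removal thus come from classes without those clusters. The other of the 4, classes by the highest marker score, counted committed OPC, oligodendrocyte and neural progenitor classes as outside the lineage. For the other changes the cause was not tested. Depth limits the small classes most, since fibroblast-like sums hold 5112895 UMIs in Control and 8271417 in Acly CKO. No paired analysis was possible because each genotype has 1 library. Pairs of shares below are Control, then Acly CKO, and other values are log2 ratios or list medians in OPC-like cells.

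500 UMIs and 250 genes as minimums gave lineage shares of 94.5% and 48.0%, cycling shares of 35.3% and 45.1%, p53 targets 0.51 and G2 and M phase in fibroblast-like cells -1.70. With the settings used for the results, G2 and M phase in fibroblast-like cells stood at 0.18 (percentile 98.22), with 15 of 19 members higher. It changed sign here and at resolution 0.5. 2000 UMIs and 1000 genes gave a lineage share of 93.2% in Acly CKO, a cycling share of 30.4% in Control and p53 targets 0.41. At most 5% mitochondrial UMIs gave lineage shares of 66.1% and 76.2%, cycling shares of 38.3% and 41.5%, cholesterol synthesis -0.092, committed OPC genes -0.12, Abca1 -0.13, Slc7a5 -0.047 and Sparc 0.17. At most 20% gave a cycling share of 41.1% in Acly CKO and p53 targets 0.42. No doublet removal gave lineage shares of 67.1% and 78.0%, cycling shares of 44.1% and 45.1%, fatty acid synthesis -0.036, cholesterol synthesis -0.073, committed OPC genes -0.10, Acly -1.26, Sparc 0.15 and Txn1 -0.036. Resolution 0.5 gave a cycling share of 29.8% in Control, p53 targets 0.41 and G2 and M phase in fibroblast-like cells -0.77. Resolution 2 gave cycling shares of 28.2% and 38.7% and p53 targets 0.41. TMM scaling gave cholesterol synthesis -0.11 and p53 targets 0.47. Totals without mitochondrial and ribosomal genes gave p53 targets 0.47. Means over cells gave fatty acid synthesis -0.036, committed OPC genes -0.21, p53 targets 0.28, Acly -1.23 and Txn1 -0.090. Thinned cells gave fatty acid synthesis -0.033, cholesterol synthesis -0.10, committed OPC genes -0.16, p53 targets 0.29, Acly -1.17, Ep300 0.047, Hacd2 -0.019, Ier5 -0.25 and Txn1 -0.046. A floor of 30 CPM gave p53 targets 0.23. A floor of 3 CPM gave p53 targets 0.46. Classes by marker score, with committed OPC and oligodendrocyte classes outside the lineage, gave lineage shares of 34.9% and 39.7% and cycling shares of 42.1% and 60.3%. Thinning before clustering gave lineage shares of 62.9% and 73.6% and a cycling share of 34.8% in Control.

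Without clusters under 0.6 of the median UMIs the values were a lineage share of 83.3% in Acly CKO, cycling shares of 34.8% and 50.8%, fatty acid synthesis -0.17, oxidative phosphorylation 0.046, p53 targets 0.60, glutamate receptors and channels -0.089, Acaca -0.015, Acly -1.50, Acss1 -0.049, Apoe -0.022, Ftl1 0.078, Ldha 0.025, Nfasc -0.10, Ptp4a3 0.039 and Spon1 -0.043. At 0.65 the gene and list values in OPC-like cells were the same, with cycling shares of 33.8% and 47.6% and a lineage share of 82.4% in Acly CKO. A cycling boundary of 0.1 gave cycling shares of 17.6% and 26.2%, p53 targets 0.38 and Abca1 -0.0089. Without the cluster rich in p53 targets the values were p53 targets 0.12 and Txn1 -0.014. The same weight for clusters gave cholesterol synthesis -0.080, oxidative phosphorylation 0.047, committed OPC genes -0.16, p53 targets 0.18, Abca1 -0.39, Acaca -0.0028, Acly -1.45, Aldoc 0.071, Btg2 -0.30, Ctcf 0.0068, Dll3 -0.022, Ern1 -0.050, Ier5 -0.12, Ifit2 0.044, Lpin1 -0.013, Me1 0.023, Nkain2 -0.13, Slc7a1 -0.059 and Slc7a5 -0.19.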

Other observations

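The genes and clusters in this part were chosen after their values were seen. In fibroblast-like cells, among genes with at least 30 CPM in a library and leaving out Y-linked genes, the highest log2 ratios included the interferon-inducible genes Ifi27l2a (1.97), Oasl2 (1.52) and Isg15 (1.33). The lowest included those of Acly (-2.68), the retinoic acid-degrading enzyme gene Cyp26b1 (-2.35), Sertad1 (-2.15) and the chemokine gene Cxcl1 (-2.06). Socs3, a feedback inhibitor of cytokine signalling, stood at 60.1 CPM in Control and 14.7 CPM in Acly CKO in OPC-like cells. It is also a member of the immediate early and dissociation response list. The median of that list was lower in OPC-like (-0.28), cycling OPC-like (-0.29) and fibroblast-like cells (-0.77). In cycling OPC-like cells Socs3 had a log2 ratio of -1.96, and Stat3 stood at 185 and 107 CPM.

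OPC-like clusters differed in how far Acly was lowered. In cluster 8 Acly stood at 54.6% of Control, Esr1 at 11.46 CPM in Acly CKO, and Cdkn1a at 8.69 CPM in Control and 3.85 CPM in Acly CKO. The median log2 ratio of p53 targets there was 0.011 (-0.044 to 0.080). In cluster 0 Acly stood at 29.4% of Control, Esr1 at 44.3 CPM in Acly CKO, Cdkn1a at 0.322 and 13.3 CPM, and p53 targets at 0.21 (0.15 to 0.29). Cluster 19, a cycling cluster, had Acly at 20.7% of Control, Esr1 at 39.0 CPM in Acly CKO and p53 targets at -0.10 (-0.21 to 0.12). Clusters are not replicates, and no relation across them was tested. Barcodes with at least 500 UMIs numbered 10749 in Control and 18364 in Acly CKO.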
